A study of Rattus norvegicus with 16 samples.

How the data were processed

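Bulk RNA sequencing was done on hippocampus, a brain region needed for memory, from male Fischer-344 rats aged 6 or 20 months. Per the labels' protocols, rats of each age either went through exercise training or stayed sedentary for 10 weeks, and tissue was taken 2 days after the last behavioral test. Total RNA was extracted with Trizol, poly(A) RNA was selected, and libraries were made with NEBNext kits and sequenced on an Illumina HiSeq instrument, per the labels' protocols. The labels' protocols name 5 libraries per condition and 10 libraries per lane. The table analysed here holds 4 libraries per group, 16 in all. The lane of each library is not given in the sources used here, so lane and group cannot be told apart.

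The deposited values are raw gene counts, whole numbers with no normalization, for 32754 Ensembl gene IDs. The submitters' processing notes name FastQC, Trimmomatic, TopHat2 2.1.1, SAMtools, HTSeq and DESeq2, and the genome build Rnor_6.0. The strand setting of the counting is not given in the sources used here, so overlapping genes, antisense genes and near-identical copies are uncertain. Library totals ran from 8630396 to 14576687 counts. Of the 32754 IDs, 23249 had a count in at least 1 library, and 15035 passed the filter on low counts and were tested.

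The count table does not pair IDs with gene symbols. The reference gene table used here, of assembly GRCr8, matched 0 of the IDs. The 38 gene lists fixed before the data were examined were therefore not tested, and genes are given by ID. The fixed rule for named genes took, per comparison, the largest rises and falls among genes with adjusted p below 0.05, a mean log2 CPM (counts scaled to a common library size) of at least 1 and a gene symbol. After the data were seen, the symbol criterion was dropped and the rule was limited to 1 rise and 1 fall in each of the 2 averaged comparisons.

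Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr by group, libraries were scaled by TMM, and a model with 1 mean per group was fitted over all 16 libraries with glmQLFit (robust), leaving 12 residual degrees of freedom. Contrasts were tested with glmQLFTest, 2-sided, and p-values were adjusted by Benjamini-Hochberg over the genes tested. A gene was called at adjusted p below 0.05. The standard error of a log2 fold change was its size divided by the square root of the F statistic. The biological coefficient of variation was 13.7%. The 7 contrasts were aging in sedentary rats, aging in trained rats, training in young rats, training in old rats, the interaction of age and training, aging averaged over training and training averaged over age. Principal components were taken from log2 CPM with a prior count of 2, and group differences were tested by exact permutation, 2-sided, in a family of 8 tests: 6 on the first component, 1 on total counts and 1 on genes with a count. The second component was not tested. No library pair of a group agreed within sampling noise. p-values measure the spread between separate rats, per the labels.

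The test was checked on simulated counts with 200 changed genes. For training averaged over age, 66.7% of genes changed 1.5-fold, 87.0% of those changed 2-fold and 98.5% of those changed 4-fold were recovered among 14893 genes. For aging in sedentary rats the shares were 53.0%, 76.5% and 95.5% among 14907 genes. These counts were simulated separately for each gene. They hold no variation that many genes share, so recovery in the data may differ. Intervals from counts cover counting error only.

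For the share of genes that went the opposite way in comparisons with the same old sedentary libraries, 20 simulations drew old trained libraries unchanged from the old sedentary means, with the other groups at their own means. A further 20 simulations, added after the data were seen, drew all groups from the old sedentary means. Simulated shares over lists of fixed length, the 227 or 200 genes of lowest p, were also added after the data were seen. The old sedentary libraries were also split 2 and 2 between the comparisons in all 6 ways.

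Alternatives chosen before the data were examined were DESeq2 size factors, the DESeq2 1.42.0 Wald test, limma 3.58.1 voom with sample quality weights, no filter and a stricter filter (at least 1 CPM in at least 8 libraries), a replicate block, 1 surrogate variable from sva 3.50.0, leaving out each library, fitting only the 8 libraries compared, and only genes with mean log2 CPM of at least 4. Added after the data were seen were 2 surrogate variables, a covariate summing 11 genes with at most 3 counts in every trained library, leaving out old sedentary libraries 1, 2 and 4, and thinning every library to the smallest total.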

Results

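Hippocampal gene expression was measured in 4 groups of 4 male Fischer-344 rats: young sedentary, young trained, old sedentary and old trained. Fischer-344 is an inbred rat strain widely used in studies of aging. The young rats were 6 months old and the old rats 20 months old. Total counts per library averaged 11501097 ± 2094603 (SD, n = 4) in young sedentary, 12148554 ± 900859 (SD, n = 4) in young trained, 11023948 ± 347837 (SD, n = 4) in old sedentary and 12063240 ± 2359110 (SD, n = 4) in old trained rats. Genes with at least 1 count ranged from 18145 to 19268 per library.

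The libraries separated first by training. The first principal component held 46.9% of the variance of log2 CPM. All 8 trained libraries lay between -39.8 and -18.9 on it, and all 8 sedentary libraries lay between 0.7 and 55.9. The trained and sedentary means differed by -57.0 (exact permutation p = 0.000155, the smallest it can give with 8 against 8, adjusted p = 0.00124 over 8 tests). Pooled over training, old and young libraries were not separated on this component (exact permutation p = 0.293, n = 8 per age). Within each training state the old mean was higher. The difference was 28.5 in sedentary rats (exact permutation p = 0.0857, adjusted p = 0.137) and 7.34 in trained rats (exact permutation p = 0.171, adjusted p = 0.229), with n = 4 per group. Trained minus sedentary was -46.4 in young and -67.6 in old rats. Each had an exact permutation p = 0.0286, the smallest that 4 against 4 can give, and adjusted p = 0.0762. The sedentary libraries were spread out: old sedentary replicate 3 lay at 12.7, while the other old sedentary libraries lay between 49.7 and 55.9. The second component, with 13.9% of the variance, had a mean of 19.9 ± 19.6 (SD, n = 4) in young trained and -20.4 ± 7.70 (SD, n = 4) in old trained rats.

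**Figure D1:**
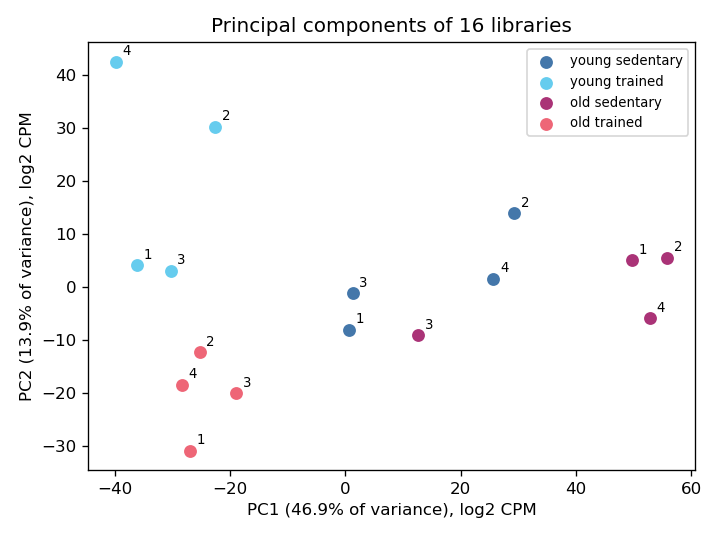
Principal components 1 and 2 of log2 CPM for the 16 libraries, in arbitrary units, with the percent of variance on each axis. Points are libraries, coloured by group and numbered by replicate, and all trained libraries lie at or below -18.9 on the first component while all sedentary libraries lie at or above 0.7.

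Whether training changed hippocampal expression was addressed first over both ages. Averaged over age, 5100 of 15035 genes (33.9%) differed between trained and sedentary rats, 2393 higher and 2707 lower in trained rats. The larger changes were mostly decreases: 589 genes were at least 2-fold lower and 155 at least 2-fold higher. The median size of a called change was 0.43 on the log2 scale, with a median standard error of 0.10. Among genes with a mean log2 CPM of at least 1, ENSRNOG00000012478 fell furthest. It stood at 16.4 ± 11.1 CPM (SD, n = 4) in young sedentary and 41.0 ± 22.1 CPM (SD, n = 4) in old sedentary rats, against 0.0219 ± 0.0439 CPM (SD, n = 4) in young trained and 0.0574 ± 0.0385 CPM (SD, n = 4) in old trained rats. Over the 8 sedentary libraries it had 2679 counts, and over the 8 trained libraries 4 counts, a ratio of 695 after scaling (95% exact binomial interval 271 to 2550, for counting error only). Its adjusted p in edgeR's quasi-likelihood test was 1.1e-05. Among the same genes ENSRNOG00000017539 rose furthest, with a log2 fold change of 2.20 (SE 0.50, edgeR adjusted p = 0.00383). It averaged 3.34 ± 1.96 CPM (SD, n = 4) in young sedentary, 7.19 ± 1.47 CPM (SD, n = 4) in young trained, 1.07 ± 1.97 CPM (SD, n = 4) in old sedentary and 10.1 ± 1.63 CPM (SD, n = 4) in old trained rats. In old sedentary replicate 3 it stood at 4.03 CPM, against at most 0.175 CPM in the others, and without that library its log2 fold change was 3.92. It did not pass with 1 surrogate variable, where the log2 fold change was 0.21 (SE 0.41), or without old sedentary libraries 1, 2 and 4, where it was 1.24 (SE 0.38). In all, 11 genes had at most 3 counts in every trained library and a mean of at least 1 CPM in sedentary libraries, and 0 genes showed the reverse. ENSRNOG00000012478 was among the 11 genes. Their summed level was 28.4 ± 19.7 CPM (SD, n = 4) in young sedentary and 68.0 ± 37.7 CPM (SD, n = 4) in old sedentary rats. A surrogate variable is estimated from the counts and is meant to hold variation not explained by the groups. With 1 such variable the count for training averaged over age was 181 genes, 50 higher and 131 lower. The median size of the 5100 changes went from 0.43 to 0.22, and their median standard error from 0.10 to 0.14. The variable thus overlapped the groups and took up part of their difference. Leaving out old sedentary libraries 1, 2 and 4, a setting chosen after the data were seen, gave 1862 genes.

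**Figure D2:**
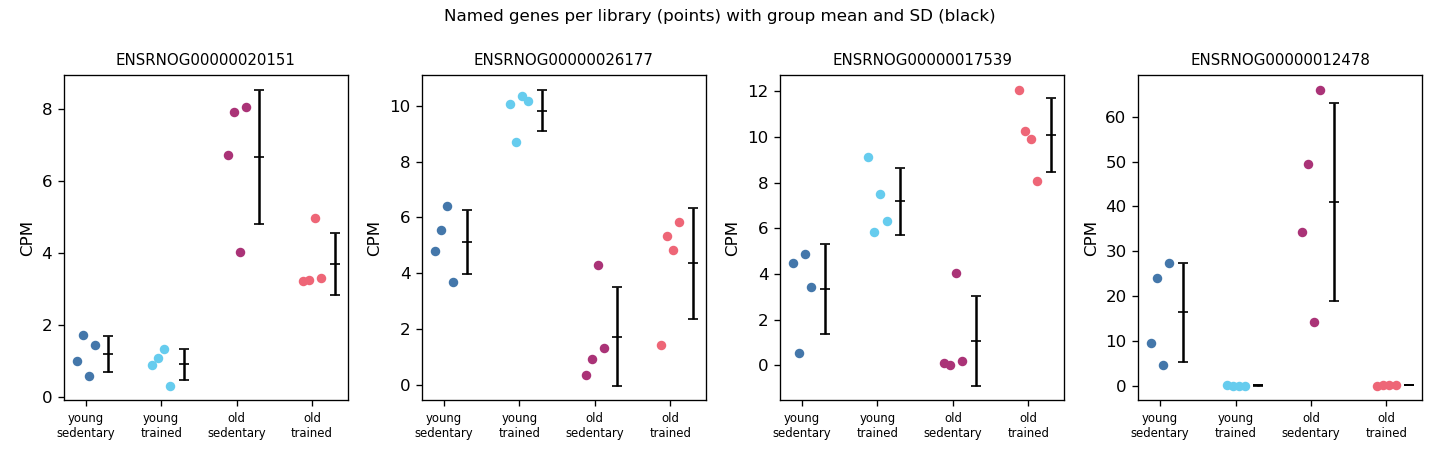
Level in CPM of the 4 genes named here in each of the 16 libraries. Points are libraries, and the black bar with its error bar is the group mean and SD (n = 4), with ENSRNOG00000012478 at most 0.0878 CPM in every trained library.

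In young rats, training was associated with 2572 called genes, 1020 higher and 1552 lower. In old rats the count was 3618, with 1729 higher and 1889 lower. The means in these comparisons come from no library in common, but the spread of each gene came from 1 fit over all 16 libraries. The lists are therefore not fully independent, and numbers expected from independent lists are only a rough guide. The comparisons called 511 genes higher in both, where 117 would be expected from independent lists. They called 860 genes lower in both, where 195 would be expected. Only 2 genes were called in opposite directions, where 307 would be expected. Across the 15035 genes, which are not independent replicates, the training fold changes of young and old rats had Pearson r = 0.69 and Spearman rho = 0.56. Leaving out 1 library gave Pearson values from 0.596 to 0.734, and without a filter on low counts the value was 0.266. With 1 surrogate variable, 1462 genes were called in young rats and 3 in old rats. limma voom called 4330 genes in young rats. In settings added after the data were seen, 2 surrogate variables gave 612 genes in young and 2 in old rats, the covariate of near-zero genes gave 1345 and 7, and leaving out old sedentary libraries 1, 2 and 4 gave 0 in old rats in edgeR, with 1251 at an unadjusted p below 0.05. The covariate tracks training by construction, because its genes were picked for a near-zero level in every trained library. In young rats, leaving out young sedentary replicate 4 gave 1295 genes and leaving out young trained replicate 4 gave 1368.

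Whether training acted differently at the 2 ages was tested by the interaction. edgeR's quasi-likelihood test called 0 of 15035 genes, with a lowest adjusted p of 0.254, and 2033 genes had an unadjusted p below 0.05. The DESeq2 Wald test called 44 genes and limma voom with sample quality weights called 0. Without old sedentary replicate 3 the edgeR test called 583 genes, and without young trained replicate 3 it called 5.

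**Figure D3:**
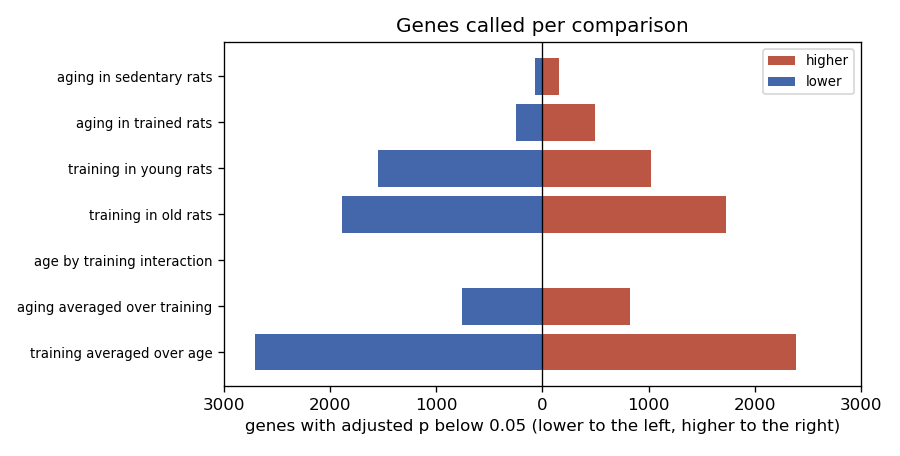
Genes with an adjusted p below 0.05 in edgeR's quasi-likelihood test for each comparison. Bars to the right count genes higher in the trained or old rats and bars to the left genes lower, with 2393 higher and 2707 lower for training averaged over age.

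Age differences were compared first over both training states. Averaged over training, 1585 genes were called, 828 higher and 757 lower in old rats, with a median size of 0.38 on the log2 scale and a median standard error of 0.09. At least 2-fold changes were found in 47 genes that were higher and 26 that were lower. Among genes with a mean log2 CPM of at least 1, ENSRNOG00000020151 rose furthest, by a log2 fold change of 2.25 (SE 0.24, edgeR adjusted p = 3.96e-05). It averaged 1.18 ± 0.499 CPM (SD, n = 4) in young sedentary and 6.67 ± 1.86 CPM (SD, n = 4) in old sedentary rats, and 0.902 ± 0.437 CPM (SD, n = 4) in young trained and 3.68 ± 0.853 CPM (SD, n = 4) in old trained rats. ENSRNOG00000026177 fell furthest among them, with a log2 fold change of -1.36 (SE 0.32, edgeR adjusted p = 0.0155). It averaged 5.11 ± 1.15 CPM (SD, n = 4) in young sedentary, 1.72 ± 1.76 CPM (SD, n = 4) in old sedentary, 9.84 ± 0.752 CPM (SD, n = 4) in young trained and 4.36 ± 2.00 CPM (SD, n = 4) in old trained rats. With 1 surrogate variable the count was 524 genes, and ENSRNOG00000026177 no longer passed (log2 fold change -1.02, SE 0.28, against -1.36, SE 0.32). In settings added after the data were seen, 2 surrogate variables gave 394 genes, the covariate 580, and leaving out old sedentary libraries 1, 2 and 4 gave 111, of which 83.8% were higher, against 52.2% of the 1585. Without old sedentary replicate 3 the count was 2451 genes, and without young sedentary replicate 3 it was 987.

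In trained rats, 748 genes were called for age, 500 higher and 248 lower in old rats. The count was 355, 454 and 241 without young trained replicates 1, 2 and 4, and 294, 487 and 327 without old trained replicates 1, 2 and 3. It was 1244 with the DESeq2 Wald test, 1286 with limma voom, 1191 with 1 surrogate variable and, in settings added after the data were seen, 319 with 2 surrogate variables and 1234 without old sedentary libraries 1, 2 and 4. In sedentary rats the count was 227, with 158 higher and 69 lower. That count rested on single libraries: it was 1991 without old sedentary replicate 3 and 44 and 41 without young sedentary replicates 1 and 3. Without old sedentary replicates 1, 2 and 4, each left out alone, it was 45, 94 and 58. It was 147 without young trained replicate 1 and 140 without old trained replicate 2. The DESeq2 Wald test called 909 genes, of which 40.0% were higher, against 69.6% with edgeR. limma voom called 405, of which 43.2% were higher, and a replicate block gave 560, of which 48.9% were higher. A fit to the 8 sedentary libraries alone called 24 genes, and 1 surrogate variable left 9, with 100% higher in both. Of 35 splits of the 8 sedentary libraries, 3 gave at least 227 genes, the real one included, so chance was not excluded for this count.

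The means in the age comparisons in sedentary and in trained rats come from no library in common. The spread of each gene came from 1 fit over all 16 libraries, so these lists are not fully independent either. The comparisons called 75 genes higher in both, where 5.25 would be expected from independent lists. They called 9 genes lower in both, where 1.14 would be expected, and 0 genes in opposite directions, where 4.9 would be expected. Of the 227 genes called in sedentary rats, 218 (96.0%) had the same sign in trained rats, and of the 748 genes called in trained rats, 601 (80.3%) had the same sign in sedentary rats. Across all 15035 genes the age fold changes had Pearson r = 0.162 and Spearman rho = 0.231, with Pearson values from 0.0695 to 0.232 on leaving out 1 library and a jackknife standard error of 0.163, as large as the value itself. The Pearson value was 0.0228 without a filter on low counts, 0.31 over genes with a mean log2 CPM of at least 4, 0.402 with 1 surrogate variable, and, in settings added after the data were seen, 0.361 with 2 surrogate variables and 0.312 without old sedentary libraries 1, 2 and 4. A score over the 748 genes called in trained rats, each taken in the direction of its change there and set against the young sedentary mean, was devised after the principal components were seen. It lay between 0.19 and 0.28 log2 units in the 4 old sedentary libraries and between -0.10 and 0.07 in the 4 young sedentary libraries (exact permutation p = 0.0286, 2-sided, the smallest that 4 against 4 can give, with the test chosen after the scores were seen).

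All 227 genes called for age in sedentary rats had the opposite sign for training in old rats (100%). Of them, 158 were also called there in the opposite direction. Independent lists would give 27.8, but these lists share the old sedentary libraries, so 27.8 is not what chance would give here. With 1 surrogate variable only 9 genes were called for age in sedentary rats and 3 for training in old rats, which ends nearly all of these joint calls. Both comparisons use the old sedentary libraries, which alone gives a share above 50%. With simulated unchanged old trained libraries and the other groups at their observed means, the share averaged 69.2% over 20 simulations (67.0% to 71.9%). These called a median of 1466.5 genes for age, against 227 in the data. With no effect in any group the share averaged 93.2% (90.5% to 95.5%) over the 200 genes of lowest p, with a median of 0 genes called. Over lists of 227 genes of lowest p, the length of the observed list, the shares averaged 72.6% (66.1% to 79.7%) and 92.8% (90.3% to 94.7%). With the old sedentary libraries split between the comparisons, the share ran from 90.9% to 95.5% over 6 splits. In 3 of the splits it was taken over 19 to 22 called genes, and in the others over 764 to 1555, where it ran from 91.1% to 94.0%. The covariance of the fold changes was -0.143, against a simulated -0.0233 with unchanged old trained libraries.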

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

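The tests of depth were chosen after the results were seen. The fit with 1 surrogate variable and the splits of the old sedentary libraries were chosen before the data were examined, but their use to weigh these explanations came after their values were seen. The tests of other splits and of a wrong label were set before their own values were seen, the latter after the principal components were seen. Of 40 sets of 4 libraries examined, 6 had a library far from the rest. For independent sets of normal values, chance marks about 5%, or about 2 of 40. These sets reuse the same libraries, and those of ENSRNOG00000012478 rest on differences of 1 count. No excess over chance is therefore read from the 6.

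Old sedentary replicate 3 lay at 12.7 on the first principal component, while the other old sedentary libraries lay between 49.7 and 55.9. Its depth of 10789527 counts was within the range of the others, which argues against depth. A young library under a wrong label would have an age score within the young sedentary range, which ended at 0.07 (SD 0.07). The score was 0.19, which argues against that label error on this score alone. The score is not set by age only. It ran from 0.07 to 0.24 in old trained and from -0.65 to -0.46 in young trained libraries, which were used to choose its genes. A difference between rats or in the tissue taken stays open and was not tested.

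Many genes differed between trained and sedentary libraries. Of 100 splits within age groups 1 gave as many genes as the real 5100, the real split itself, and the highest other gave 2. That argues against chance, though a share of 1 of 100 is the least this test can give. After thinning to 1 depth 4567 genes were called, which argues against depth. With 1 surrogate variable 1462 genes were called in young rats, so the variation that variable held is not the whole cause there. With 2 the count was 612, and variation within groups that such variables do not hold was not tested. In old rats 3 were called with 1 surrogate variable. There the median fold of the called genes went from 0.61 to 0.20 on the log2 scale and its standard error from 0.15 to 0.22. Training and variation among libraries of a group cannot be told apart there. Sequencing lane or library batch, given for 0 of the groups, cannot be told apart from training either. A difference in the tissue taken was not tested. It stays open, as does an effect of training itself.

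Genes called for age in sedentary rats went the opposite way with training in old rats. The lowest share over splits of the old sedentary libraries was 90.9%, over 22 called genes, and 91.1% among splits with at least 764 called genes, which argues against sampling noise of the shared libraries as the whole cause. With 1 surrogate variable the share was 85.0%, taken over the 200 genes of lowest p because fewer than 10 were called. Simulations without a surrogate variable gave 66.5% to 80.0% over 200 such genes with unchanged old trained libraries and 90.5% to 95.5% with no effect in any group. The share lay between these ranges. Both simulations drew the variation among libraries separately for each gene, so neither holds variation that many genes share. Such variation among libraries of a group cannot be told apart from an effect of training.

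The other splits gave these counts. For training in young rats 1 of 35 splits reached the real 2572, and the highest other gave 0. For training in old rats 1 of 35 reached 3618, and the highest other gave 717. For aging in trained rats 1 of 35 reached 748, and the highest other gave 0. For aging averaged over training 1 of 100 reached 1585, and the highest other gave 18. These counts argue against chance, though 1 of 35 and 1 of 100 are the least these tests can give. No adjustment was made over the comparisons. For aging in sedentary rats 3 of 35 reached 227, so chance is not excluded. The highest other split gave 1401, several times the real count, which points to a structure of the samples. This split exchanged old sedentary replicate 3 with young sedentary replicate 2. It parted the sedentary libraries by their place on the first principal component, 0.7 to 25.7 against 29.3 to 55.9. Another split gave 774 genes. For the interaction all 100 splits reached the real 0, and the highest other gave 0. Any split reaches a count of 0, so this says nothing about chance.

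ENSRNOG00000020151 stood at 4.96 CPM in old trained replicate 3, against 3.23 to 3.31 CPM in the others. ENSRNOG00000026177 stood at 8.73 CPM in young trained replicate 2, against 10.09 to 10.36 CPM. ENSRNOG00000017539 stood at 4.03 CPM in old sedentary replicate 3, against at most 0.175 CPM. ENSRNOG00000012478 stood at 0.0878 CPM in young trained replicate 1, against 0 in the others, and at 0 in old trained replicate 1, against 0.0719 to 0.0808 CPM, differences of 1 count.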

How the results depend on the processing

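The tests with 2 surrogate variables, the covariate of 11 near-zero genes, the 3 old sedentary libraries left out and thinning were chosen after the data were seen. The cause of the changes given here was not tested, except that fits with fewer libraries had fewer samples. DESeq2 size factors, the stricter filter and thinning left every count of genes within 1.5 times. For training averaged over age and training in old rats every fit without 1 library also stayed within 1.5 times.

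Aging in sedentary rats gave 227 genes. The count was 909 with the DESeq2 Wald test, 405 with limma voom, 24 with only the 8 libraries compared, 9 with 1 surrogate variable, 14 with 2, 12 with the covariate and 3 without old sedentary libraries 1, 2 and 4, where the remaining library was assumed to vary like the other groups. With limma voom 43.2% of the calls were higher. Aging in trained rats gave 748 genes, and 1244 with the DESeq2 Wald test, 1286 with limma voom, 1191 with 1 surrogate variable, 319 with 2 and 1234 without the 3 old sedentary libraries. Training in young rats gave 2572 genes, and 4330 with limma voom, 1462 with 1 surrogate variable, 612 with 2 and 1345 with the covariate. Training in old rats gave 3618 genes, and 3 with 1 surrogate variable, 2 with 2, 7 with the covariate and 0 without the 3 old sedentary libraries, where 1251 genes had an unadjusted p below 0.05 in edgeR. The interaction gave 0 genes, and 44 with the DESeq2 Wald test. Aging averaged over training gave 1585 genes, and 524 with 1 surrogate variable, 394 with 2, 580 with the covariate and 111 without the 3 old sedentary libraries. Training averaged over age gave 5100 genes, and 181, 237, 437 and 1862 in the same order. There 1 surrogate variable took the median fold of the called genes from 0.43 to 0.22 on the log2 scale and its standard error from 0.10 to 0.14.

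Leaving out 1 library gave 41 to 1991 genes for aging in sedentary rats, 241 to 1071 for aging in trained rats, 1295 to 2989 for training in young rats, 0 to 583 for the interaction and 987 to 2451 for aging averaged over training. The correlation of age fold changes, 0.162, was 0.402 with 1 surrogate variable, 0.361 with 2, 0.312 without the 3 old sedentary libraries, 0.31 over genes with mean log2 CPM of at least 4 and 0.0228 without a filter, with a jackknife standard error of 0.163. The correlation of training fold changes, 0.69, was 0.266 without a filter. The share of opposite direction was 100% over 227 called genes. It was 78.6% over the 14 genes called with 2 surrogate variables and 75% over the 12 called with the covariate. Over the 200 genes of lowest p, used because 9 and 3 genes were called, it was 85.0% with 1 surrogate variable and 89.5% without the 3 old sedentary libraries. These shares are not over the same genes. Of the named genes, ENSRNOG00000020151 and ENSRNOG00000012478 passed under every alternative run. ENSRNOG00000026177 and ENSRNOG00000017539 did not pass with 1 or 2 surrogate variables, the covariate or the 3 libraries left out. For ENSRNOG00000017539 these took the log2 fold change from 2.20 to 0.21, 0.58, 0.18 and 1.24, and for ENSRNOG00000026177 from -1.36 to -1.02, -1.14, -1.07 and -0.69.

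The replicate numbers were not taken to pair the samples, since in no comparison were all 4 correlations of same-numbered libraries above 0.1. They ran from -0.245 to 0.477, 9 of 16 were above 0.1, and 7 of 16 libraries correlated best with their own number. A replicate block gave 560 genes for aging in sedentary rats, of which 48.9% were higher against 69.6% without it, and left the other counts within 1.5 times. The gene list alternatives, with an estimated correlation or with quality weights, were not run, since the lists were not tested.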

Other observations

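Genes that were at least 2-fold lower in trained rats were not at 1 level in the sedentary rats. Over 251 such genes with a mean log2 CPM of at least 2, leaving out the 11 near-zero genes, the median level relative to the sedentary mean was 0.634 and 0.635 in young sedentary replicates 1 and 3, and 1.08 and 1.02 in replicates 2 and 4. Among the old sedentary libraries it was 0.733 in replicate 3 and 0.936 to 1.36 in the others. In the trained libraries it ran from 0.265 to 0.429. Over 94 genes that were at least 2-fold higher in trained rats, old sedentary replicate 3 stood at 1.29, against 0.355 to 0.469 in the other old sedentary libraries, 1.09 to 1.66 in the young sedentary libraries and 1.70 to 2.83 in the trained libraries. These genes were chosen for their difference between trained and sedentary libraries, and the values describe the libraries only.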
